A study of Drosophila melanogaster with 4 samples.

How the data were processed

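Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Drosophila melanogaster embryos of the y cn bw sp strain with a guinea pig polyclonal serum raised against Homothorax, the product of hth (CG17117). The stage label reads 0 to 8 h. The labels' extract protocol, which all 4 libraries share, opens with an 8 to 16 h laying window and then describes an 8 h lay, so the protocol text and the stage label differ; the stage label was used. Embryos were cross-linked in 1.8% formaldehyde for 15 min, per the labels' protocols. The 4 libraries form 2 groups according to their titles, 2 Homothorax ChIP libraries and 2 input DNA libraries.

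One peak table of the whole series was analysed. Per the file headers, its coordinates are on FlyBase release 5 and each line was written by MACS, a peak caller that tests the ChIP read pile-up against the input. The submitters' processing notes name the build BDGP5, the base-calling software CASAVA (versions 1.7.0.2 and 1.7.0.3), the aligner BWA and MACS2, without a version for the last 2. The table gives a start, an end and a score for each peak as the authors deposited it. What the score measures (a fold, or the size of a p- or q-value) is not given in the sources used here. It was used to rank, filter and describe peaks within this list. Later comparisons that divide scores or take their logarithm depend on this unknown scale. Whether the ChIP replicates were pooled before calling, the calling threshold and any excluded regions are likewise not given in the sources used here. The read depth of the libraries is unknown from this table, and no value belongs to a single library. ChIP and input, and the replicates of each, therefore could not be compared here, and no replicate error exists for any peak. The p-values below measure the spread of positions or scores within this one list, in which peaks are not independent replicates.

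The gene table at hand describes release 6 of the genome, so its positions were not used with the release 5 peaks, and no genome sequence was used here. The planned tests of peak position relative to genes, of 16 gene lists and of the Homothorax recognition motif were not run for this reason. Peaks and regions are named by position, 1-based on release 5, with no statement on the gene, exon, intron or UTR at any of them. The rule fixed for this case before the data were examined names the 10 peaks with the highest score and the 5 windows of 100 kb, tiled from position 1, with the most peak centres. Any other region named was chosen after its values were seen.

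All calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Peak width is the end minus the start plus 1 bp, and the centre is the midpoint. Tests used the peaks on the 6 arms 2L, 2R, 3L, 3R, 4 and X, apart from the test of Uextra scores. Since the arm lengths of release 5 are not in the table, an arm was taken to reach from position 1 to the end of its last peak, which leaves out any peakless tip. Peak numbers per arm were compared with 10000 random placements over the arms in proportion to this extent, two-sided, with Benjamini-Hochberg adjustment over the 6 arms. Because uniform placement treats clustered peaks as independent and can understate the spread, density on X was also compared with the 4 large autosome arms by permuting the labels of whole 1 Mb bins (10000 permutations, two-sided), a test added after the data were seen. Intervals on density are 95% bootstrap intervals over whole 1 Mb bins. Clustering was the share of peaks with another peak centre within 10 kb, compared with 1000 random placements of the same number of centres on each arm, two-sided. Random centres were allowed to lie on top of each other. A run was defined as consecutive peaks separated by gaps of at most 5 kb.

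The tests were tried on simulated lists of 5894 peaks on the same arm extents, 40 lists per setting. With peaks placed uniformly, the placement test called X in 0, the bin test in 1 and the clustering test in 2 of 40 lists. With X density multiplied by 0.5, both X tests called 40 of 40, with a mean recovered ratio of 0.5004. With part of the peaks moved next to others, the clustering test called 40 of 40. The placement test called X in 2 of 40 of these lists and the bin test in 1 of 40. Peak numbers per arm were drawn uniformly before the move, and each moved peak stayed on its arm. These lists therefore cannot show how clustering affects the X tests. The alternatives tried were the 50% of peaks with the highest score, merging of peaks closer than 1 kb, distances of 5 and 50 kb for clustering and, added after the data were seen, arm extents counted from the first peak, merging and random placement inside 1 Mb bins for clustering, windows shifted by 50 kb, the highest-scoring 50% for the densest windows and removal of 1 block of wide peaks on 2L. The expectation per arm spans all 6 arms, so a deficit on one arm raises the ratio of the others.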

Results

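The binding of Homothorax was mapped in whole embryos labelled 0 to 8 h. Homothorax is a homeodomain protein of the TALE class that binds DNA together with Extradenticle, carries Extradenticle into the nucleus, and acts with it as a cofactor of the Hox proteins. The question addressed is where on the genome Homothorax is bound at this stage, from 2 ChIP libraries and 2 input DNA libraries of one strain. The authors' peak table holds 6207 peaks, none of which overlaps another, and they cover 4742 kb in all. Peak width had a median of 483 bp, an interquartile range of 303 to 850 bp and a minimum of 201 bp. The authors' score ran from 5.80 to 379.52 with a median of 16.93. A score of 40 or more was held by 1088 peaks (17.5%), and 100 or more by 268 peaks (4.32%). Wider peaks scored higher, with a Spearman rho of 0.81 across peaks, which are not independent replicates. The depth of the libraries is unknown, and replicate agreement was not analysed here.

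The highest-scoring peaks lay on chromosomes 2 and 3. Of the 10 highest, 6 were on 2L, 2 on 3L and 2 on 3R. The top score, 379.52, belonged to a peak at 2L 14426979 to 14458909, which at 31.9 kb was also the widest of the list. Others of the top 10 came from the same stretch of 2L. They lay at 14469186 to 14491422 with a score of 340.68, at 14552058 to 14565347 with a score of 330.10, and at 14495989 to 14503050 with a score of 302.73. The second highest peak of the list, at 2L 21852662 to 21858385, was 5.72 kb wide and scored 375.76. A compact 988 bp peak at 2L 5403360 to 5404347 scored 289.85, the tenth highest value. On 3L, the peak at 14570435 to 14572637 scored 351.64 and the peak at 14964455 to 14966238 scored 310.98. On 3R, the peak at 8470493 to 8476138 scored 325.39 and the peak at 2862328 to 2863923 scored 306.85. No error can be attached to these scores, since each is a single value for the series, so the order of neighbouring ranks is descriptive.

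Homothorax peaks were less dense on X than on the large autosome arms. X carried 603 peaks, or 27.1 per Mb (95% bootstrap interval 21.3 to 33.3 over 22 bins of 1 Mb), which was 0.542 times the number that uniform placement gives (adjusted p = 0.0003, permutation by random placement, the smallest these draws and the adjustment gave). The 4 large autosome arms carried 61.3 peaks per Mb on 2L (interval 50.9 to 75.0), 59.0 on 3L (47.0 to 71.7), 55.1 on 3R (41.9 to 70.5) and 46.3 on 2R (36.7 to 55.3). Per whole 1 Mb bin, X held 27.1 ± 14.8 peaks (SD, n = 22 bins) and the 4 autosome arms 55.6 ± 31.8 (SD, n = 92 bins), a ratio of 0.488 (p = 0.0001, two-sided permutation of bins, the smallest the permutations can give). The 4 large autosome arms did not differ from each other beyond the spread between their bins: the highest and lowest arm means were 16.5 peaks apart (p = 0.30, permutation of bins). The small chromosome 4 held 45 peaks, 33.5 per Mb and 0.671 times the number from uniform placement (adjusted p = 0.0065, permutation by random placement). That call was lost when peaks closer than 1 kb were merged (ratio 0.818, adjusted p = 0.34 by permutation), whereas among the 50% of peaks with the highest score the ratio fell to 0.428 (adjusted p = 0.0012 by permutation), below the 0.503 of X. With 1 whole bin on the arm no bin test was possible.

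**Figure D1:**
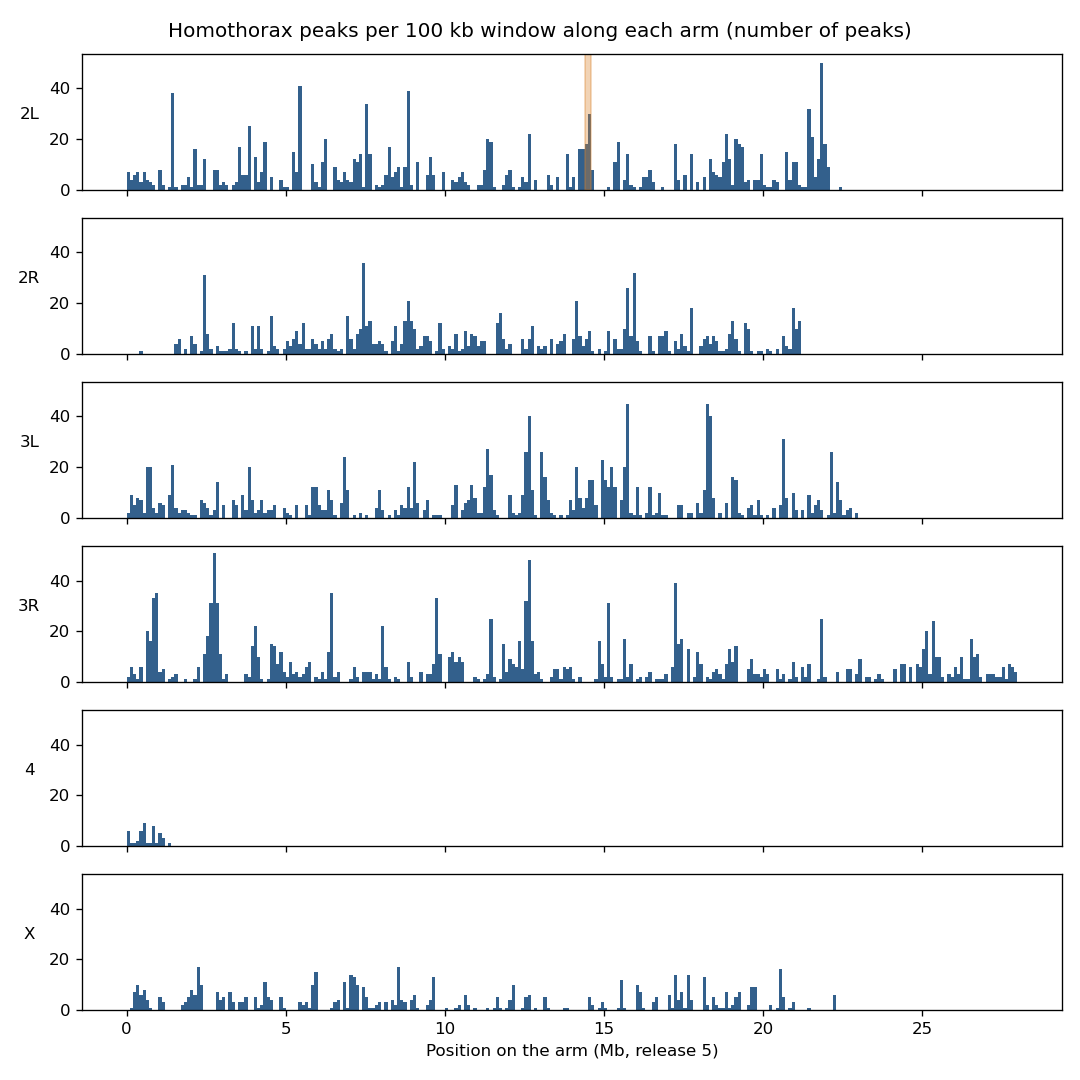
Number of Homothorax peak centres per 100 kb window (y axis, shared scale) along the 6 arms (x axis, Mb, release 5), 1 bar per window. Peaks gather in narrow columns separated by sparse stretches, X has lower columns than the large autosome arms, and the shaded band on 2L marks the block of wide peaks.

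High scores were also less frequent on X. The median score was 15.07 on X and 13.59 on chromosome 4, against 17.07 on 2L, 16.93 on 3L, 16.53 on 2R and 16.18 on 3R. Median width was 429 bp on X and 378 bp on chromosome 4, against 484 to 513 bp on the large autosome arms. Within whole 1 Mb bins, 13.1% of X peaks and 18.9% of peaks on the large autosome arms scored 40 or more, a difference of -5.82 percentage points (p = 0.0001, two-sided permutation of bins). The shortfall on X grew with the score. Peak density on X was 0.487 times that of the autosome arms for all peaks, 0.442 times at a score of 20 or more, 0.336 times at 40 or more and 0.229 times at 80 or more. At 160 or more, X had 3 peaks and the 4 autosome arms 89. The highest score was 183.96 on X and 44.54 on chromosome 4.

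**Figure D2:**
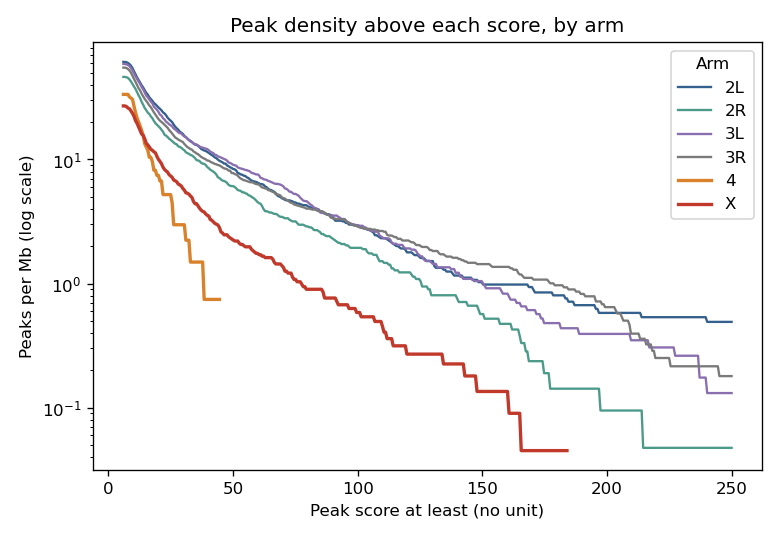
Peaks per Mb (y axis, log scale) with at least the score on the x axis, drawn up to 250, 1 line per arm. The X line lies below those of 2L, 2R, 3L and 3R at each score drawn and ends at 183.96, and the line of chromosome 4 ends at 44.54.

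Peaks occurred in groups along the arms. On the 6 arms, 88.3% of 5894 peaks had another peak centre within 10 kb, whereas random placement on the same arms gave 64.4% on average and at most 66.6% (p = 0.002, two-sided permutation by random placement, the smallest the 1000 draws can give). The median distance to the nearest peak was 1.39 kb on 2L, 1.41 kb on 3R, 1.49 kb on 3L, 1.56 kb on 2R, 1.64 kb on X and 1.70 kb on chromosome 4. Within 10 kb of another peak lay 91.0% of the peaks on 2L, 81.6% of those on X and 71.1% of those on chromosome 4. Runs of 10 or more peaks with gaps of at most 5 kb numbered 106 and held 1794 peaks, 30.4% of those on the arms. A further 993 peaks (16.8%) stood alone. Within 50 kb the share lay slightly below random, at 97.8% of peaks against 98.9% in random placements. This share depends only on the few peaks without a neighbour and does not show even spacing at that distance.

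**Figure D3:**
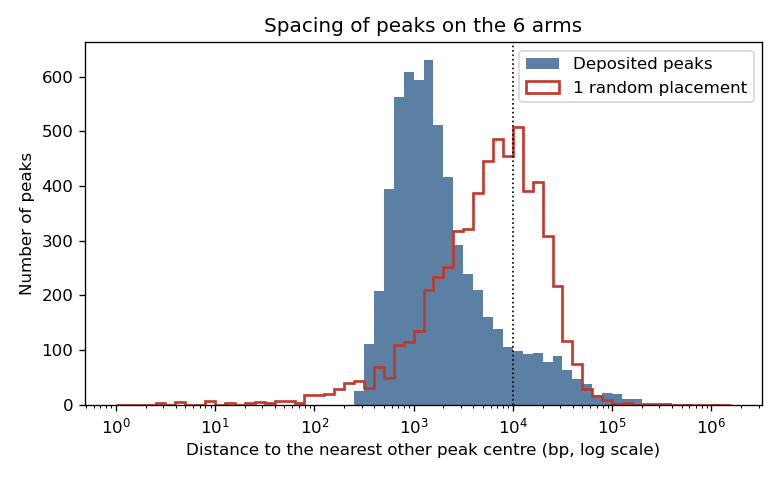
Histogram of the distance from each peak centre to the nearest other centre (x axis, bp, log scale; y axis, number of peaks) for the 5894 peaks on the arms and for 1 random placement of as many centres. The dotted line marks 10 kb; 88.3% of the deposited peaks lie to its left.

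The densest windows were on 3R, 2L and 3L. The window at 3R 2.7 to 2.8 Mb held 51 peak centres with a top score of 270.82. The window at 2L 21.8 to 21.9 Mb held 50, whose peaks added up to 62.2 kb, and included the second highest peak of the list. The window at 3R 12.6 to 12.7 Mb held 48 with a top score of 219.07. On 3L, the windows at 15.7 to 15.8 Mb and at 18.2 to 18.3 Mb held 45 each, with top scores of 113.52 and 227.20. The mean over all 1184 windows was 4.98 ± 7.15 peaks (SD across windows) with a median of 2, and no window of 1000 random placements held more than 20. At the other end, 329 windows (27.8%) held no peak. The longest stretch between peaks was 1136 kb, at 2R 404790 to 1540396, and the longest on X was 766 kb, at X 21465623 to 22231774. The stretch on 2R followed the first peak of that arm, which starts at 404525. That on X ended close to the last peak, which ends at 22.26 Mb. Whether reads can be mapped in these stretches was not examined, and random placement could put centres there. With windows shifted by 50 kb, a different window was densest, at 3R 0.85 to 0.95 Mb with 57 peaks.

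One block on 2L stood apart in peak width and was singled out after its values were seen. The run from 14416154 to 14588444, 172 kb long, held 44 peaks that covered 88.3% of it. The most covered other stretch of that length, at 2L 21403867 to 21576157, was 53.3% covered. It contained a shorter run, at 2L 21451050 to 21543478, that was 76.7% covered over its own 92.4 kb. The contrast with the block therefore depends in part on the length compared. The block contained the 3 widest peaks of the list, at 31.9, 22.2 and 13.3 kb, while the widest peak outside it was 11.5 kb, at 2R 9447263 to 9458738 with a score of 196.92. Of its peaks, 13 scored 100 or more and 19 were over 2 kb wide. The longest gap inside the block was 3.61 kb, beyond its end no peak was listed for 38.7 kb, and the gap before its start was 7.71 kb. Without the block, 2L still carried 1.20 times the peaks of uniform placement, compared with 1.23 times with it, both over all 6 arms, where the low number on X raises the ratio of the other arms.

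**Figure D4:**
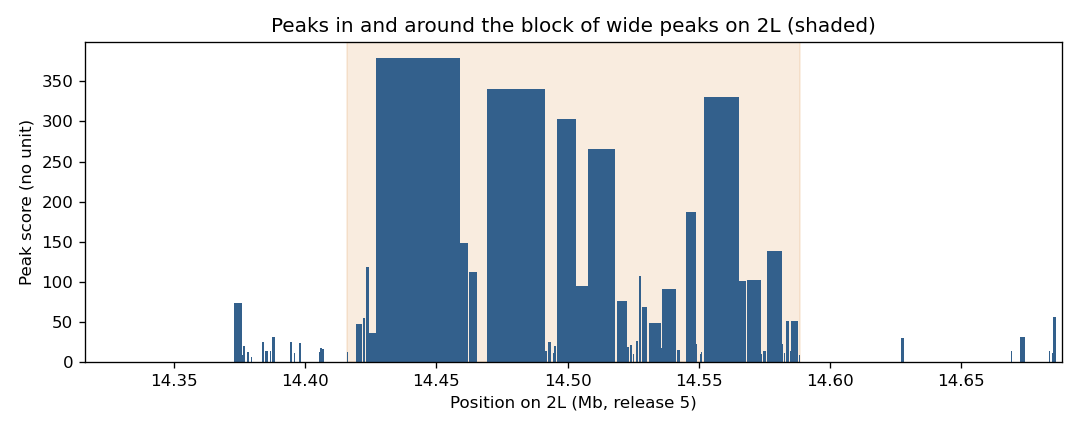
Peaks in and around the block at 2L 14416154 to 14588444 (shaded), each drawn to scale from its start to its end (x axis, Mb, release 5) with its score as height (y axis, no unit). Peaks cover 88.3% of the shaded stretch, and 38.7 kb without a peak follow it.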

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

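The density of X and the clustering within 10 kb were tested as set down before the data were seen. The tests of explanations for them, and those on the 2L block and on Uextra scores, were chosen afterwards.

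Peaks outside the 6 arms entered no test on arms, clustering or neighbouring scores, but are part of the values for the whole list. They numbered 313, of which 303 were on Uextra, 9 on U and 1 on 2RHet, sequences of release 5 that hold unplaced scaffolds and heterochromatin. They make up 5.04% of the list and were noted because they are a signal outside the main measurement. No control value is listed for them, nor for the peaks on the arms. Uextra peaks had a median score of 19.67, above the 16.54 of the arms (p = 0.001, two-sided permutation of scores over peaks), but their upper quartile was lower, 24.74 against 30.24, as was their highest score, 108.35 against 379.52. No Uextra peak was wider than 1053 bp, while 6.79% of the peaks on the arms were over 2 kb. The lengths of the unplaced scaffolds were not known here, so whether they limit peak width was not examined. Wider peaks scored higher in this list, so the same limit applies to the upper scores.

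The first pattern weighed is the low peak density on X. Fewer sites with the autosomal range of scores would leave the share of high scores alike, and that share was lower on X (p = 0.0001, permutation of bins), which argues against fewer sites as the whole cause. At equal peak density the autosomal score was 2.03, 2.07, 2.08 and 2.00 times the X score at 2, 5, 10 and 20 peaks per Mb, with 95% bootstrap limits between 1.59 and 2.71, from 994 resamples in which X reached each density. The highest of these ratios was 1.04 times the lowest. All levels were read from the same ranked peaks, and a ratio of scores depends on their unknown scale and zero. A common factor on X scores may therefore describe these values but is not shown by them. Whether a lower X dose in embryos of unstated sex gives that factor cannot be told apart from weaker occupancy of X, because the scale of the score and the depth per arm are not given in the sources used here.

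The second pattern is the clustering of peaks. A broad enriched region cut into pieces by the peak caller could bring it about, but after merging of peaks closer than 1 kb 72.5% of the remaining 3438 still had a neighbour within 10 kb, against at most 48.5% in random placements. Regional density over 1 Mb gave at most 70.2% in placements inside the bins, below the observed 88.3%. Both results argue against these explanations as the whole cause, and splitting at gaps over 1 kb stays untested. Grouping of Homothorax sites remains a hypothesis, and no biological explanation was tested.

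The third pattern is the 172 kb block on 2L. A higher copy number in the ChIP chromatin than in the input would give nearly gapless cover, abrupt ends and low scores for the width. Since the block was chosen after its wide peaks were seen, the 88.3% of it inside peaks is no support for this account. Its end was followed by 38.7 kb without a peak, but its start was preceded by a gap of only 7.71 kb, and the first and last peaks scored 12.44 and 8.85, so an abrupt edge was seen on 1 side at most. For their width, the block's peaks over 2 kb scored a median of -0.36 on the log2 scale against the trend of all other peaks. That lay inside the 95% range of -1.53 to 1.20 of 31 other runs with at least 3 such peaks. Low scores for the width were therefore not shown. Copy number and strong sites packed closely cannot be told apart, because coverage per library, which would separate them, was not analysed here. No biological group of the design bears on the block.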

How the results depend on the processing

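Chosen after the data were seen were the merging of peaks as applied to clustering, random placement inside 1 Mb bins, the permutation of bins, arm extents from the first peak, removal of the 2L block, the shifted windows and the highest-scoring 50% as applied to the densest windows; the others were fixed before. Among the 50% of peaks with the highest score, 3107 peaks remained. The X deficit and the clustering within 5 and 10 kb kept their direction and their side of the threshold in every setting run on them. So did the ratios of 2L and 3L to uniform placement, but that expectation spans all 6 arms, so the X deficit raises the ratio of every other arm, and the 4 large autosome arms did not differ beyond the spread between their bins (p = 0.30, permutation of bins). The deficit on 2R (0.928 times uniform placement, adjusted p = 0.010 by permutation) was lost among the 50% highest-scoring peaks (0.923) and after merging of peaks closer than 1 kb (0.989). The same merging ended the calls for 3R (1.05) and chromosome 4 (0.818). At 55.1 peaks per Mb, 3R lay close to the 55.6 of the 4 large autosome arms pooled, so its ratio above 1 is no excess among them. The placement test treats neighbouring peaks as independent, and merging leaves fewer peaks to test. X ranged from 0.503 times uniform placement among the highest-scoring peaks to 0.640 after merging. The share within 50 kb lay below random (97.8% against 98.9%), a distance at which it is close to its ceiling. Peak numbers per window of 100 kb were uneven, with 57 windows that held 20 or more peaks. The highest number in any window of the random placements was 20. Those placements moved each peak singly and did not keep runs together. The count therefore does not separate unevenness over longer distances from the clustering within 10 kb. Of 31 alternatives to the tested results, 26 kept the direction and the call. The 5 densest windows held 19 to 27 peaks among the highest-scoring 50%. No paired analysis was possible because the table holds no values per library, and for the same reason no replicate could be left out. The other settings set down beforehand, for gene features, gene lists and the motif, were not run, since no release 5 annotation or sequence was used here. Depth limits could not be set because read depth is unknown.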

Other observations

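Runs with many closely spaced Homothorax peaks differed in make-up, leaving aside the block on 2L described above. The run with the most peaks, at 2L 21788757 to 21899724, held 56 in 111 kb with a top score of 375.76. The next by number of peaks, at 2L 5390419 to 5493029, held 45 in 103 kb with a top score of 289.85. The run at 2L 21451050 to 21543478 held 38 peaks that covered 76.7% of 92.4 kb, yet its highest score was 37.65. On 3R, the run at 6415929 to 6499955 held 35 peaks over 84.0 kb with a top score of 217.75, and the run at 899275 to 952268 held 36 over 53.0 kb with a top score of 208.74. These runs were chosen after their values were seen. No genome sequence was used, so repeated sequence in these runs was not examined and its part in their peaks is unknown.

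A hypothesis that high-scoring peaks lie beside high-scoring peaks was set down before its test and did not hold. The scores of adjacent peaks over 5 kb apart had a Spearman rho of 0.0402 over 2135 pairs (p = 0.084, two-sided permutation of scores within arms), below the highest of 1000 permuted values, 0.0759. Over all 5888 adjacent pairs rho was -0.01 (p = 0.47, permutation). Peaks are not independent, and the test does not bound a relation within subsets of the genome.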
